A study of Mus musculus with 22 samples.

How the data were processed

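Ribosome profiling and RNA sequencing were run on quadriceps muscle of C57Bl/6 mice, an inbred laboratory strain, fasted overnight and given leucine or vehicle by mouth 30 minutes before the tissue was taken. Per the labels' protocols, total RNA was extracted with QIAzol, depleted of ribosomal RNA, fragmented and made into libraries with a small RNA kit. For footprints, crude polysomes were digested with RNase, monosomes were collected through sucrose, and the protected fragments were depleted of ribosomal RNA and made into libraries with the same kit. The libraries were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, Bowtie and edgeR were used with mouse genome build mm9, and their versions are not given in the sources used here. How reads that match several places were handled is also not given there. Ribosomal protein genes have many near-identical pseudogenes, so the counts of single members are uncertain.

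The authors deposited a table of whole-number counts per gene for the 22 libraries, with gene symbols and transcript identifiers, and every column of samples was used. It lists 6054 genes, of which 95 carry a noncoding identifier, 146 have a predicted-gene or clone symbol and 9 have a symbol turned into a date. No value lies below 129 counts, so the authors' table appears to hold abundant genes only. Total counts ranged from 15016267 to 30944085 in RNA libraries and from 21697096 to 48996109 in footprint libraries, so counting error was small beside the spread between libraries. The authors also deposited a table of edgeR results per assay, with log2 fold changes, p-values and FDR values per the file headers. These tables were used only for description, in sentences that name them. Samples were grouped by the treatment and assay in their labels. The column names match groups but carry no replicate number, so libraries could not be paired across assays by label, and the efficiency model treats them as unpaired. They carry 2 prefixes that the sources used here do not explain, called sets A and B, and libraries are named by group, set and column order within the set.

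Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, robust quasi-likelihood fits and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. The filter removed 0 genes. Leucine was compared with vehicle in the 11 RNA libraries, in the 11 footprint libraries, and, for translational efficiency, as the interaction of treatment and assay in 1 model over all 22 libraries. Log2 changes are leucine minus vehicle, with standard errors. CPM are counts scaled to a common total with the TMM-adjusted library size. Changes are thus relative to the other genes, and a change in total footprints or total RNA cannot be seen.

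The 29 gene lists, the comparisons, the tests, the rule for named genes and the first set of processing alternatives were fixed before the data were examined. The lists are cytosolic ribosomal proteins, elongation factors and other TOP mRNAs (mRNAs that start with a run of pyrimidines), initiation factors, aminoacyl-tRNA synthetases, ribosome biogenesis, amino acid sensing and mTORC1 signalling, ATF4 and amino acid response, fasting and FoxO-linked atrophy genes, glucocorticoid-induced genes, proteasome subunits, nuclear-encoded oxidative phosphorylation, mitochondrial ribosomal proteins, fast-fibre sarcomere and calcium handling, slow-fibre and cardiac sarcomere, glycolysis and glycogen, fatty acid oxidation, branched-chain amino acid catabolism, immediate early genes, circadian clock genes, heat shock and endoplasmic reticulum chaperones, and sterol and fatty acid synthesis. The other lists mark endothelial cells, fibroblasts and matrix, adipocytes, macrophages and leukocytes, erythroid cells, smooth muscle and pericytes, Schwann cells and nerve, and satellite cells and junctions, since the tissue was taken whole. The 24 lists with at least 5 measured members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry (its directional p), each adjusted over the lists of a comparison. Camera compares a list with the other genes, while fry asks whether its genes move 1 way on balance. A list score is the mean over members of log2 CPM with a prior count of 1, centred on the mean of the assay's libraries. Scores were compared with an exact two-sided permutation test over 462 splits of 11 libraries, whose smallest possible p is 0.00216, and over the 200 splits that keep the sets, each adjusted over 24 lists. Those tests and the division by sets were added after the data had been seen.

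Genes were named by a rule with 3 parts. In each comparison these were the 10 largest positive and 10 largest negative changes among genes past the threshold with a mean count of at least 20, or, where a direction had fewer than 3 such genes, its 3 genes with the smallest p. From each list came up to 4 members with the smallest p. The third part was a fixed set of mTORC1, translation, amino acid response, atrophy and muscle genes, of which Asns and Sesn2 are not analysed here. Predicted-gene, clone and date symbols were counted and not named. Genes named outside this rule are marked as such, and some genes that the rule takes are not reported here.

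The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, the edgeR exact test, no count filter, a mean count of at least 50, removal of the 20 most abundant genes, a non-robust fit, an adjusted p under 0.1, and leaving out each library in turn. After the data had been seen, a mean count of at least 500, the set as a covariate in edgeR or DESeq2, and each set alone were added. On simulated counts for the 6054 genes, the edgeR test recovered 25.4%, 79.1% and 95.5% of genes changed 1.25-, 1.5- and 2-fold in the footprint design, and 7.45% of its calls were false. In the RNA design it recovered 10.4%, 65.7% and 90.9%, with 8.09% false, and in the efficiency design 5.97%, 31.3% and 86.4%, with 7.34% false. In the same simulations 19.3%, 18% and 13.9% of DESeq2 calls were false in the RNA, footprint and efficiency designs. The simulated counts held no difference between the sets and no correlation between genes, so the rates in the data can differ.

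Coding length, codon content, transcript starts and predicted N-terminal hydrophobic segments came from a GENCODE mouse transcript set of a later genome build, used for sequence properties only, with no coordinates. By identifier 5977 genes were matched, by symbol 36, and 41 were not matched.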

Results

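Skeletal muscle responds to leucine, a branched-chain amino acid known to activate the kinase complex mTORC1, and the study asked which mRNAs change in translation. Quadriceps muscle was taken from fasted mice 30 minutes after an oral dose of leucine or vehicle. RNA sequencing measured transcript abundance. Ribosome profiling measured footprints, the mRNA fragments that ribosomes protect from nuclease. There were 5 vehicle and 6 leucine RNA libraries, and 5 vehicle and 6 leucine footprint libraries. Total counts ran from 15016267 to 27305083 in vehicle RNA, from 17941961 to 30944085 in leucine RNA, from 24432316 to 48996109 in vehicle footprints and from 21697096 to 47646844 in leucine footprints. Ttn, which encodes the giant sarcomere protein titin, took 24.1% ± 2.59 of counts in vehicle RNA (SD, n = 5) and 23.3% ± 1.61 in leucine RNA (SD, n = 6). Its share of footprints was 5.91% ± 0.538 in vehicle (SD, n = 5) and 5.33% ± 0.403 in leucine (SD, n = 6).

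The labels do not say that the libraries come from separate animals, so p-values measure the spread between these samples. Pearson correlations of log2 CPM within a group lay between 0.93 and 0.9937, and every pair of libraries of a group differed by more than counting noise. In each assay set A held 3 vehicle and 3 leucine libraries and set B held 2 vehicle and 3 leucine libraries. With treatment in the model, 1139 genes differed between the sets in RNA and 1441 in footprints. The edgeR test of a treatment difference between the sets called 0 genes in both assays, with 110 genes in RNA and 176 in footprints at an unadjusted p under 0.05. This test was not run with another tool. Leucine RNA library A3 stood apart on the principal component that held 47.5% of the RNA variance, and its Eef2 and Rpsa levels were the lowest of its group.

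Footprints on mRNAs of the translation machinery were higher in leucine muscle. All 74 measured cytosolic ribosomal protein genes had a positive footprint change, with a median of 0.68 on the log2 scale (1.61-fold), and 27 of them rose individually. The 19 measured elongation factors and other TOP mRNAs, a class whose translation is known to depend on mTORC1, also all had positive changes, with a median of 0.41 (1.33-fold), and 7 rose. Of 6054 genes, 42 rose and 4 fell, with adjusted p between 0.0479 and 0.0497 in edgeR's quasi-likelihood test. Among the 42 were 39 members of the lists, all of them in translation or glycolysis. The other 3, named after their values were seen, were Cmc1 (0.38), Pwp1 (0.29) and the prefoldin subunit gene Pfdn5 (0.67). All 6 leucine values lay above all 5 vehicle values in 106 genes and below all of them in 45, where chance gives 13.1 in each direction on average. Genes move together, so this number can vary widely between regroupings, and its spread was not computed.

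Rps2, a protein of the small ribosomal subunit, went from 23.8 ± 5.53 CPM in vehicle (SD, n = 5) to 56.1 ± 19.1 CPM in leucine (SD, n = 6), a log2 change of 1.23 ± 0.24 (SE). Eef2, the factor that moves the ribosome along the mRNA, went from 195.8 ± 35.9 to 419 ± 139 CPM, a change of 1.10 ± 0.22. Rpsa rose from 31.5 ± 4.17 to 61.8 ± 18 CPM, and Rplp0, a protein of the ribosomal stalk, from 38.8 ± 7.96 to 77.2 ± 22.5 CPM. Tpt1, a TOP mRNA that encodes the tumour protein TCTP, rose from 159.3 ± 25.5 to 282.5 ± 71 CPM. Large rises were also seen for Rpl8 (0.86 ± 0.16), Rpl24 (0.82 ± 0.16), Rpl27a (0.82 ± 0.16) and Rps18 (0.82 ± 0.17). The ribosomal protein genes with the smallest p were Rpl7 (0.70 ± 0.12), Rpl23 (0.63 ± 0.11), Rpl22 (0.65 ± 0.12) and Rpl36a (0.73 ± 0.13), and all 4 rose.

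The rise in ribosomal protein footprints covered nearly the whole list, with 72 of 74 members higher when adjusted over the list alone. The members that missed this were Rpl3 and Rpl36al, named after their values were seen. Compared with other genes, the list moved up with adjusted p = 2.32e-107 by camera, but adjusted p = 0.0643 with an estimated correlation did not pass. Fry, which does not compare the list with other genes, gave adjusted p = 0.0108. Its score rose by 0.655 ± 0.143 (SE), and all 6 leucine libraries lay above all 5 vehicle libraries (adjusted p = 0.026, exact two-sided permutation test over 24 lists). Within sets the median was 0.55 in A and 0.81 in B. Among elongation factors and other TOP mRNAs, 18 of 19 were higher when adjusted over the list alone (camera adjusted p = 1.5e-27, adjusted p = 0.0643 with an estimated correlation, and fry adjusted p = 0.0108). Besides Eef2 and Tpt1, the initiation factor 3 subunits Eif3f (0.61 ± 0.11), Eif3e (0.46 ± 0.08) and Eif3h (0.38 ± 0.07) and the nucleolar chaperone Npm1 (0.51 ± 0.10) rose. Eef1a1, which delivers aminoacyl-tRNA to the ribosome, changed by 0.34 ± 0.14 (adjusted p = 0.367) and the poly(A)-binding protein gene Pabpc1 by 0.29 ± 0.15 (adjusted p = 0.461), neither past the threshold. The list score was higher by 0.473 ± 0.0945 (SE), by 0.411 within set A and by 0.539 within set B, again with all 6 leucine libraries above all vehicle libraries (adjusted p = 0.0259, exact two-sided permutation test). In the plot of list scores by library, these separations and the one for glycolysis can be read off.

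**Figure D1:**
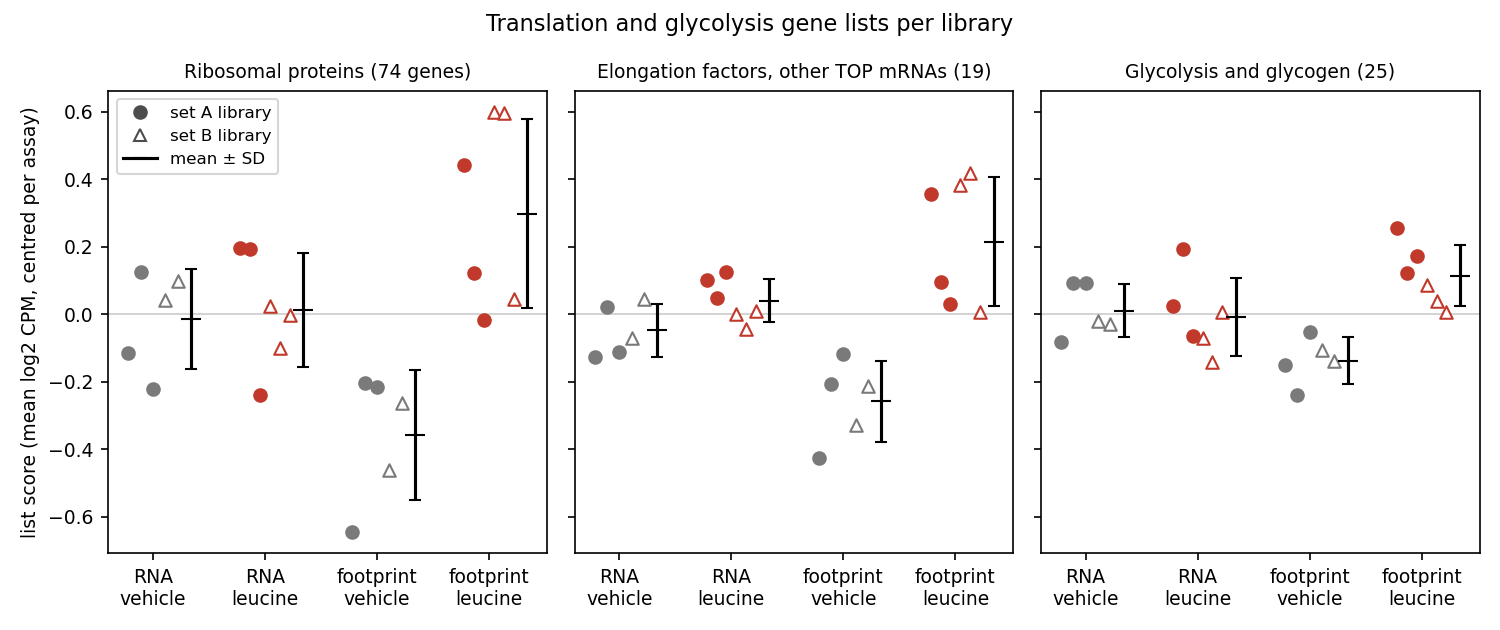
Footprint and RNA list scores (mean log2 CPM of the list's members, centred within each assay) for 74 ribosomal protein genes, 19 elongation factor and other TOP genes and 25 glycolysis and glycogen genes, with 1 point per library, filled circles for set A, open triangles for set B, and the group mean with SD. In footprints all 6 leucine libraries lie above all 5 vehicle libraries in each panel, while the RNA scores of the groups overlap.

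Other parts of the protein synthesis machinery moved less. The initiation factors had a median of 0.10 with 24 of 33 positive; Eif2a (0.52 ± 0.10) and Eif3k (0.36 ± 0.07) rose, and 5 members were higher when adjusted over the list alone (camera adjusted p = 1.95e-05, adjusted p = 0.0935 with an estimated correlation). Their score was higher by 0.12 ± 0.0271 (SE; adjusted p = 0.026, exact two-sided permutation test, and adjusted p = 0.048 when permuted within sets). All 6 leucine libraries lay above all 5 vehicle libraries, though the lowest leucine value (-0.00996) barely exceeded the highest vehicle value (-0.00997). Eif4a2, an RNA helicase of the cap-binding complex, changed by 0.68 ± 0.15 (adjusted p = 0.0501), Eif3i by 0.40 ± 0.09 (adjusted p = 0.0542) and the cap-binding repressor gene Eif4ebp1 by 0.14 ± 0.15 (adjusted p = 0.755). Of 22 aminoacyl-tRNA synthetases and their partners, which charge tRNAs with amino acids, 20 were positive with a median of 0.09. Aimp1 (0.48 ± 0.09) and Qars (0.43 ± 0.09) rose, 4 members did so when adjusted over the list alone, and the list call (camera adjusted p = 6.59e-06) had adjusted p = 0.178 with an estimated correlation. The synthetase score was higher by 0.14 ± 0.0341 (SE; adjusted p = 0.026, exact two-sided permutation test, and adjusted p = 0.03 when permuted within sets). In 5 of 6 leucine libraries it lay above all vehicle libraries. The values of Kars (0.25 ± 0.07) and Cars (0.23 ± 0.07) did not pass. Ribosome biogenesis genes had a median of 0.08 and 15 of 22 positive, and 0 members passed, also when adjusted over the list alone (camera adjusted p = 0.00374, adjusted p = 0.178 with an estimated correlation). The score, higher by 0.0839 ± 0.0278 (SE), did not pass (adjusted p = 0.0521, exact two-sided permutation test, and adjusted p = 0.0686 when permuted within sets). The biogenesis genes with the smallest p were the helicase gene Ddx21 (0.28 ± 0.08), Mybbp1a (0.24 ± 0.07), Bop1 (0.17 ± 0.06) and Nop2 (0.24 ± 0.09).

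Glycolysis and glycogen genes also had more footprints. The median over 25 members was 0.20, 23 were positive, and Aldoa, the muscle aldolase, rose from 10330 ± 807 CPM in vehicle (SD, n = 5) to 16050 ± 2310 CPM in leucine (SD, n = 6), a change of 0.64 ± 0.11 (SE). Adjusted over the list alone, 10 members were higher (camera adjusted p = 2.92e-09, adjusted p = 0.0935 with an estimated correlation). Fry gave adjusted p = 0.0108. Ldha (0.50 ± 0.11, adjusted p = 0.0548), which interconverts pyruvate and lactate, the glycogen phosphorylase gene Pygm (0.41 ± 0.09, adjusted p = 0.0575), the glycogen primer gene Gyg (0.65 ± 0.15, adjusted p = 0.0753) and the creatine kinase gene Ckm (0.50 ± 0.13, adjusted p = 0.108) stayed short of the threshold over all genes. The list score was higher by 0.251 ± 0.0481 (SE; adjusted p = 0.0259, exact two-sided permutation test), by 0.331 in set A and by 0.166 in set B.

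Genes of the contractile apparatus of fast fibres had a median of 0.14 with 28 of 36 positive. None passed over all genes and 5 were higher when adjusted over the list alone (camera adjusted p = 4.69e-05, adjusted p = 0.178 with an estimated correlation). Fry gave adjusted p = 0.0406. The list score was higher by 0.167 ± 0.0483 (SE; adjusted p = 0.026, exact two-sided permutation test, and adjusted p = 0.06 when permuted within sets). All 6 leucine libraries lay above all 5 vehicle libraries. Actn3, the fast-fibre actinin, had 0.78 ± 0.17 (adjusted p = 0.0548), the intermediate filament gene Des 0.69 ± 0.17 (adjusted p = 0.0868), the calcium channel gene Cacna1s 0.48 ± 0.13, Mybpc2 0.72 ± 0.21, Acta1 0.52 ± 0.16 and the myosin gene Myh4 0.32 ± 0.14. The slow-fibre list had 3 measured members (Actc1 0.42 ± 0.54, Atp2a2 -0.15 ± 0.30 and Tpm3 0.01 ± 0.17) and was not tested.

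Further lists passed with camera, and each of their calls was lost with an estimated correlation. For oxidative phosphorylation 69 of 77 members were positive (median 0.10, camera adjusted p = 2.51e-06, adjusted p = 0.607 with an estimated correlation), with Atp5g2 (0.77 ± 0.17) and Atp5g1 (0.54 ± 0.15), which encode the same subunit of ATP synthase, not passing. Mitochondrial ribosomal proteins had a median of 0.08 (54 of 70 positive; camera adjusted p = 5.78e-05, adjusted p = 0.41 with an estimated correlation), with Mrpl30 at 0.43 ± 0.14 and Mrpl52 at 0.20 ± 0.07. Fatty acid oxidation genes had a median of 0.12 (25 of 27 positive; camera adjusted p = 0.00717, adjusted p = 0.705 with an estimated correlation). The proteasome list had a median of 0.06 (25 of 33 positive; camera adjusted p = 0.0229, adjusted p = 0.613 with an estimated correlation), and Psmd6 (0.31 ± 0.07) was its 1 member higher when adjusted over the list alone. Heat shock and endoplasmic reticulum chaperones had a median of 0.05 (camera adjusted p = 0.0419, adjusted p = 0.705 with an estimated correlation), with Hsp90ab1 at 0.55 ± 0.17. The ATF4 list, genes that respond to amino acid lack, had a median of 0.12 (8 of 9 positive; camera adjusted p = 0.0419, adjusted p = 0.285 with an estimated correlation), with Gpt2 at 0.25 ± 0.08, Ddit4 at 0.64 ± 0.39 and Atf4 at 0.03 ± 0.07. In these 6 lists 0 members passed over all genes in edgeR. Their scores had adjusted p between 0.228 and 0.571 (exact two-sided permutation test). The list calls were also lost without single libraries, in some cases with a median as large as before: the chaperone call was lost without vehicle A1 (median 0.03), A2 (0.03) or A3 (0.05) or leucine B1 (0.03), B2 (0.03) or B3 (0.02), with the set as a covariate (0.03) and within set A (0.01) or set B (0.06), and the ATF4 call without vehicle A2 (0.14), B1 (0.14) or B2 (0.10) or leucine A1 (0.07), A2 (0.14) or A3 (0.12) and within set B (0.19). The proteasome call was lost without vehicle A2 (0.04) or B2 (0.03) or leucine A1 (0.05) or A3 (0.03) and within set A (0.05), the fatty acid oxidation call without vehicle A3 (0.08) or B1 (0.08) or leucine A1 (0.08) or A2 (0.10), and those of oxidative phosphorylation (0.02) and mitochondrial ribosomal proteins (0.05) within set B.

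Footprints lower relative to other genes were seen for 4 genes. Ryk, a receptor for Wnt ligands, fell from 10.1 ± 0.386 CPM in vehicle (SD, n = 5) to 7.43 ± 0.761 CPM in leucine (SD, n = 6), a change of -0.44 ± 0.08 (SE). The ubiquitin ligase gene Mib1, which acts in Notch signalling, fell from 39.5 ± 1.56 to 31.4 ± 1.83 CPM (-0.33 ± 0.06), and vehicle footprint library A1 was the lowest vehicle value at 36.8 CPM. The transcriptional repressor gene Zfp238 (-0.42 ± 0.08) and the ubiquitin ligase gene Rfwd2 (-0.35 ± 0.07) also fell. The clock gene Arntl had -0.57 ± 0.12 (adjusted p = 0.0548) and was the 1 lower member of the circadian list when adjusted over the list alone. Of 23 fibroblast and matrix markers 20 were negative, with a median of -0.20, and 0 passed, also when adjusted over the list alone (camera adjusted p = 0.000287, adjusted p = 0.41 with an estimated correlation). They included Dcn (-0.31 ± 0.12), the collagen gene Col1a2 (-0.45 ± 0.19), Mfap5 (-0.25 ± 0.11) and the matrix protease gene Mmp2 (-0.21 ± 0.09). The score of this list differed by -0.189 ± 0.107 (SE; adjusted p = 0.228, exact two-sided permutation test), by -0.184 in set A and -0.177 in set B.

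The remaining tested lists did not pass in footprints. Medians were 0.01 for amino acid sensing and mTORC1 signalling (adjusted p = 0.902), -0.03 for fasting and FoxO-linked genes (0.805), 0.12 for glucocorticoid-induced genes (0.439), -0.01 for branched-chain amino acid catabolism (0.805), -0.11 for immediate early genes (0.123), -0.0001 for the circadian clock (0.454), 0.06 for sterol and fatty acid synthesis (0.209), -0.06 for endothelial markers (0.303), 0.09 for smooth muscle and pericyte markers (0.125) and -0.05 for satellite cell markers (0.708). Mtor itself had 0.20 ± 0.08, the S6 kinase gene Rps6kb1 -0.21 ± 0.08, and the atrophy ubiquitin ligase genes Fbxo32 -0.44 ± 0.42 and Trim63 -0.08 ± 0.31, none past the threshold. With fewer than 5 measured members and no test, adipocyte markers had a median of 0.39 (3 genes), macrophage markers -0.27 (4 genes), and the Schwann cell marker Pmp22 -0.11 ± 0.12. Of the erythroid markers 0 were measured. The mTORC1 list's median was positive where its mean and test were negative, and the satellite cell list's median was negative where its mean and test were positive.

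The adjusted p of every called footprint gene lay just under 0.05, and the count depended on the tool and the libraries: it was 0 with upper-quartile scaling (833 genes at an unadjusted p under 0.05), with limma-voom (732) and without any single library except leucine A3 (84 higher, 14 lower) and leucine B3 (65 higher, 2 lower), and it was 188 higher and 65 lower in DESeq2 and 99 higher and 19 lower in the edgeR exact test. Within set A edgeR called 0 genes (539 at an unadjusted p under 0.05) and within set B 1, which was not among the 46. With the set as a covariate 46 were higher and 9 lower in edgeR, and 305 higher and 160 lower in DESeq2. The sizes of the changes moved less. Over 19 settings the log2 change of Rps2 ran from 1.05 to 1.40, of Eef2 from 0.87 to 1.30 and of Ryk from -0.47 to -0.39.

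**Figure D2:**
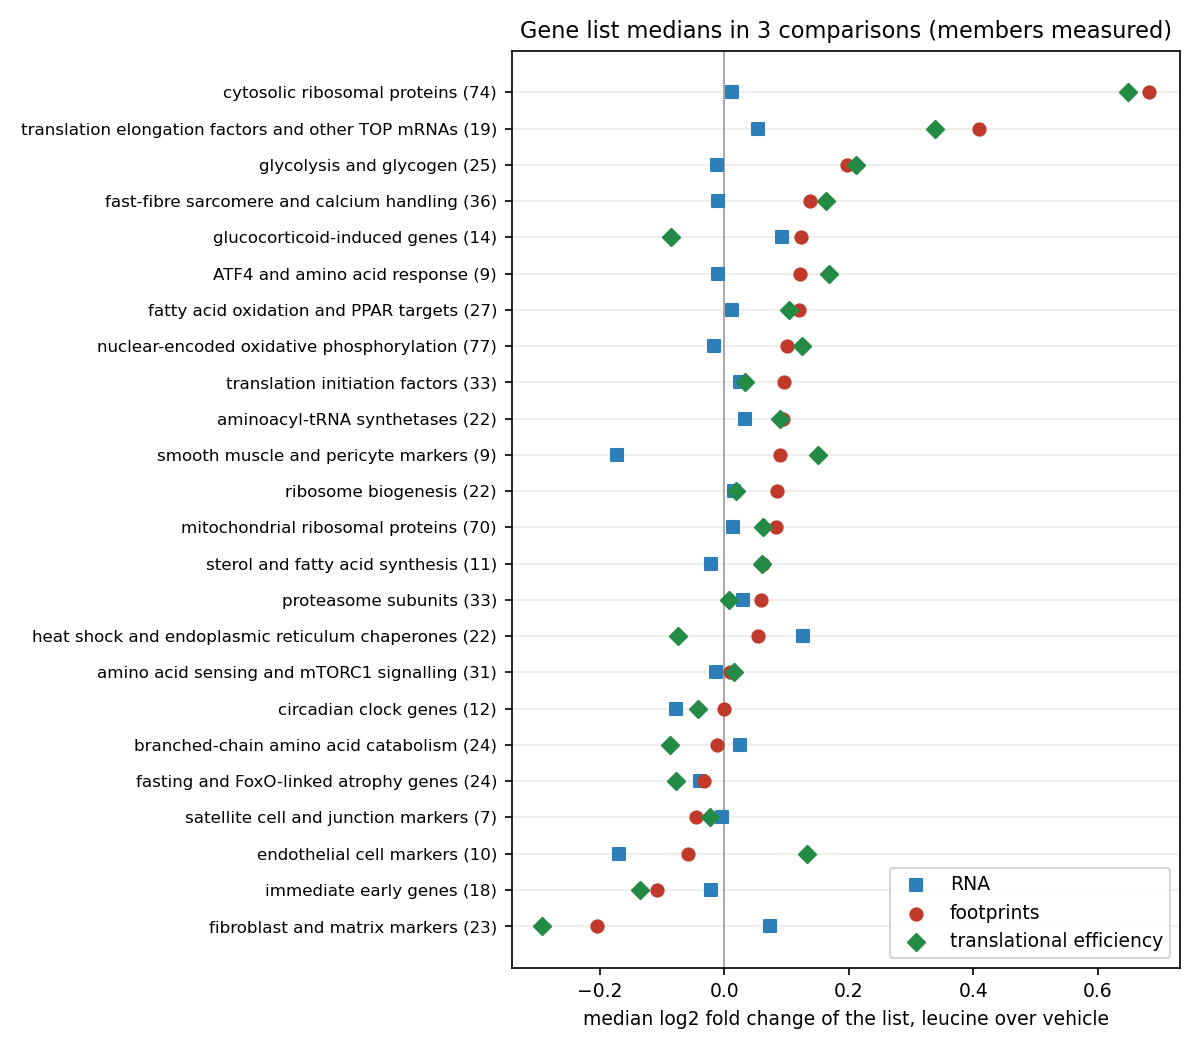
Median log2 change (leucine minus vehicle) of each of the 24 tested gene lists in RNA, footprints and translational efficiency. Ribosomal proteins have medians of 0.68 in footprints, 0.65 in efficiency and 0.01 in RNA, and the fibroblast and matrix markers have -0.20 in footprints, -0.29 in efficiency and 0.07 in RNA.

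Translational efficiency, the footprint change relative to the RNA change, was higher in leucine muscle for ribosomal proteins and for elongation factors and other TOP mRNAs. All 74 ribosomal protein genes had a positive efficiency change, with a median of 0.65 (1.57-fold), and 62 were higher when adjusted over the list alone. The list passed with camera (adjusted p = 2.12e-84), and its call held with an estimated correlation (adjusted p = 0.0368). Of the 19 elongation factors and other TOP mRNAs, 17 were positive with a median of 0.34, and 11 were higher when adjusted over the list alone (camera adjusted p = 2.65e-15, adjusted p = 0.0425 with an estimated correlation). Ribosome biogenesis genes had a median efficiency change of 0.02 and did not pass (camera adjusted p = 0.403). In vehicle muscle the ribosomal protein list had a mean log2 ratio of footprint CPM to RNA CPM of -1.58 ± 0.105 (SE, n = 5 libraries per assay), far below the mean over all genes of -0.203 ± 0.0106, and in leucine muscle it had -0.965 ± 0.131 (SE, n = 6 libraries per assay). This ratio was not corrected for coding length or for reads shared with pseudogenes.

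No single gene passed for efficiency in edgeR, with 0 called and 429 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 called 46 higher and 11 lower. These models treat the 22 libraries as unpaired. Positive changes with small p included Tpt1 (0.97 ± 0.22) and Rps13 (0.81 ± 0.18), each with adjusted p = 0.148. Rpl22 (0.66 ± 0.15), Rpl8 (0.88 ± 0.20), Eef2 (1.04 ± 0.25), Gnb2l1, which encodes the ribosome-bound scaffold RACK1 (0.76 ± 0.20), Eif3h (0.38 ± 0.10) and Eif2a (0.48 ± 0.11) also did not pass, with adjusted p between 0.148 and 0.236, while Eef1a1 had 0.17 ± 0.22 and Pabpc1 -0.35 ± 0.47. The negative changes with the smallest p were Ryk (-0.57 ± 0.12, adjusted p = 0.148), Zfp238 (-0.46 ± 0.11, adjusted p = 0.189) and Snora74a (-2.12 ± 0.55, adjusted p = 0.204), the last a small nucleolar RNA with no protein product.

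Glycolysis genes had a median efficiency change of 0.21 (23 of 25 positive; camera adjusted p = 1.29e-07, adjusted p = 0.119 with an estimated correlation), with Aldoa at 0.53 ± 0.17, Gpi1 at 0.42 ± 0.14 and Ckm at 0.53 ± 0.20. Fast-fibre genes had a median of 0.16, with Des at 0.78 ± 0.19 and Actn3 at 0.85 ± 0.23, and 2 members were higher when adjusted over the list alone (camera adjusted p = 0.000308, adjusted p = 0.212 with an estimated correlation). Oxidative phosphorylation had a median of 0.13 (camera adjusted p = 8.09e-05, adjusted p = 0.794 with an estimated correlation), mitochondrial ribosomal proteins 0.06 (camera adjusted p = 0.00164, adjusted p = 0.704 with an estimated correlation), aminoacyl-tRNA synthetases 0.09 (camera adjusted p = 0.00129, adjusted p = 0.358 with an estimated correlation) and initiation factors 0.03 (camera adjusted p = 0.00853, adjusted p = 0.316 with an estimated correlation). All 9 smooth muscle and pericyte markers were positive, with Acta2 at 0.57 ± 0.21 (median 0.15, camera adjusted p = 0.00634, adjusted p = 0.358 with an estimated correlation). Of 23 fibroblast and matrix markers 21 were negative, with Dcn at -0.55 ± 0.19 (median -0.29, camera adjusted p = 0.00101, adjusted p = 0.624 with an estimated correlation). Without RNA leucine A1 the fibroblast median was -0.11 and its call was lost, as were the calls of oxidative phosphorylation (0.02) and mitochondrial ribosomal proteins (0.01) without RNA vehicle B1, of the latter (0.03) without RNA leucine A3, and of smooth muscle markers (0.09) without RNA leucine A2. The fast-fibre (0.01) and smooth muscle (0.05) calls were lost within set B and that of initiation factors (0.03) within set A. For the mTORC1 list the median and test were positive and the mean negative, and for satellite cell markers the mean and test were positive and the median negative. Within sets the ribosomal protein efficiency median was 0.40 in A and 0.91 in B, and with the set as a covariate DESeq2 called 72 genes higher and 29 lower.

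At the RNA level few differences between leucine and vehicle muscle were detected. Ribosomal protein transcripts had a median change of 0.01 with 39 of 74 positive (camera adjusted p = 0.202). Chaperone transcripts had a median of 0.13 with 20 of 22 positive, and endothelial markers a median of -0.17 with 9 of 10 negative; both lists passed with camera and had adjusted p = 0.675 with an estimated correlation. No gene passed in edgeR's quasi-likelihood test: 0 were called, 163 had an unadjusted p under 0.05 where chance gives 303, and DESeq2 (253 at an unadjusted p under 0.05), limma-voom (155) and the edgeR exact test (101) also called 0. The smallest adjusted p in edgeR was 0.999.

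Rps2 had 252.5 ± 24.5 CPM in vehicle RNA (SD, n = 5) and 278 ± 19.3 CPM in leucine RNA (SD, n = 6), and Eef2 had 934.9 ± 36.1 and 966.6 ± 113 CPM. Ribosomal protein genes with small p included Rps16 (0.70 ± 0.25), Rps26 (0.28 ± 0.12) and Rps15a (0.27 ± 0.11). Among all genes the smallest p belonged to Brix1, which acts in large-subunit assembly (0.28 ± 0.08), the chaperone gene Hsp90ab1 (0.28 ± 0.08) and the endosomal GTPase gene Rab7 (0.45 ± 0.13) on the positive side, and to the developmental myosin gene Myh3 (-0.69 ± 0.20), Ushbp1 (-0.39 ± 0.11) and Urb1 (-0.30 ± 0.09) on the negative side.

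By camera 4 lists passed in RNA, and each of these calls was lost with an estimated correlation. Heat shock and endoplasmic reticulum chaperones (camera adjusted p = 1.1e-05, adjusted p = 0.675 with an estimated correlation) included Hsph1 (0.44 ± 0.15), Dnaja1 (0.29 ± 0.14) and the small heat shock gene Cryab (0.36 ± 0.17). Endothelial markers (camera adjusted p = 9.23e-05, adjusted p = 0.675 with an estimated correlation) included the VEGF receptor gene Kdr (-0.46 ± 0.20), Mmrn2 (-0.22 ± 0.09), Pecam1 (-0.19 ± 0.12) and Tek (-0.13 ± 0.08). Smooth muscle and pericyte markers had a median of -0.17 with 8 of 9 negative (camera adjusted p = 0.0409, adjusted p = 0.9 with an estimated correlation), with Tagln at -0.20 ± 0.13, Acta2 at -0.19 ± 0.15 and Pdgfrb at -0.32 ± 0.28. Elongation factors and other TOP mRNAs had a median of 0.05 (camera adjusted p = 0.0409, adjusted p = 0.9 with an estimated correlation), with Nap1l1 at 0.21 ± 0.07, Eif3f at 0.28 ± 0.16 and Naca at 0.79 ± 0.48. In all lists 0 members were called by edgeR, also when adjusted over the list alone, and every list score had adjusted p = 0.978 (exact two-sided permutation test).

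The other lists did not pass in RNA, with medians between -0.08 for the circadian clock (adjusted p = 0.607) and 0.09 for glucocorticoid-induced genes (adjusted p = 0.132). In the latter, Glul, which encodes glutamine synthetase, had 0.59 ± 0.20, Per1 0.49 ± 0.39 and Ddit4 0.45 ± 0.31. In fasting and FoxO-linked genes (median -0.04, adjusted p = 0.947) Fbxo32 had -0.19 ± 0.37 and Trim63 -0.21 ± 0.22. In glycolysis (median -0.01, adjusted p = 0.94) Gapdh had 0.38 ± 0.14. Oxidative phosphorylation had a median of -0.02 (adjusted p = 0.886), fibroblast and matrix markers 0.07 (adjusted p = 0.202), and sterol and fatty acid synthesis -0.02 (adjusted p = 0.828). Macrophage markers were positive in 4 of 4 measured members (median 0.22, not tested). Median, mean and test differed in sign for the fast-fibre, FoxO, fatty acid oxidation, ATF4 and satellite cell lists.

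The RNA list results depended on the libraries: set scores were 0.199 in A and 0.051 in B for chaperones, -0.366 and -0.0331 for endothelial markers, and -0.277 and 0.0215 for smooth muscle markers. The smooth muscle call was lost without vehicle A1, A3 or B1 or leucine A1, A2 or B1. The TOP call was lost without vehicle A1 or A3 or leucine A1, A2 or B1, and all 4 calls were lost within set B. Over 16 settings the smooth muscle median ran from -0.24 to 0.04 and the TOP median from 0.01 to 0.11. The chaperone median ran from 0.03 to 0.21 and the endothelial median from -0.32 to -0.06. The ribosomal protein list passed within both sets in opposite directions at the preset correlation. Its median was 0.10 in set A (camera adjusted p = 1.83e-06) and -0.12 in set B (camera adjusted p = 1.42e-05). The difference between the sets did not pass for this list (median -0.211, unadjusted p = 0.209 in camera with an estimated correlation). The list also passed without vehicle A2 (0.04), vehicle B1 (0.03), vehicle B2 (0.03), leucine A3 (0.06) or leucine B2 (0.04). With the set as a covariate DESeq2 called 11 genes higher and 1 lower.

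Across the 6054 genes no relation of footprint and RNA changes was seen. Pearson's r was -0.00156 ± 0.216 and Spearman's rho 0.0391 ± 0.165 (jackknife SE over 22 libraries). This spread allows a positive or a negative relation. In RNA 163 genes had an unadjusted p under 0.05 where chance gives 303, so values near 0 do not show that the changes are unrelated. Genes are not independent replicates, so no p is given. Without the ribosomal protein genes the values were -0.0116 and 0.0361 over 5980 genes. Within sets r was 0.123 in A and -0.193 in B.

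**Figure D3:**
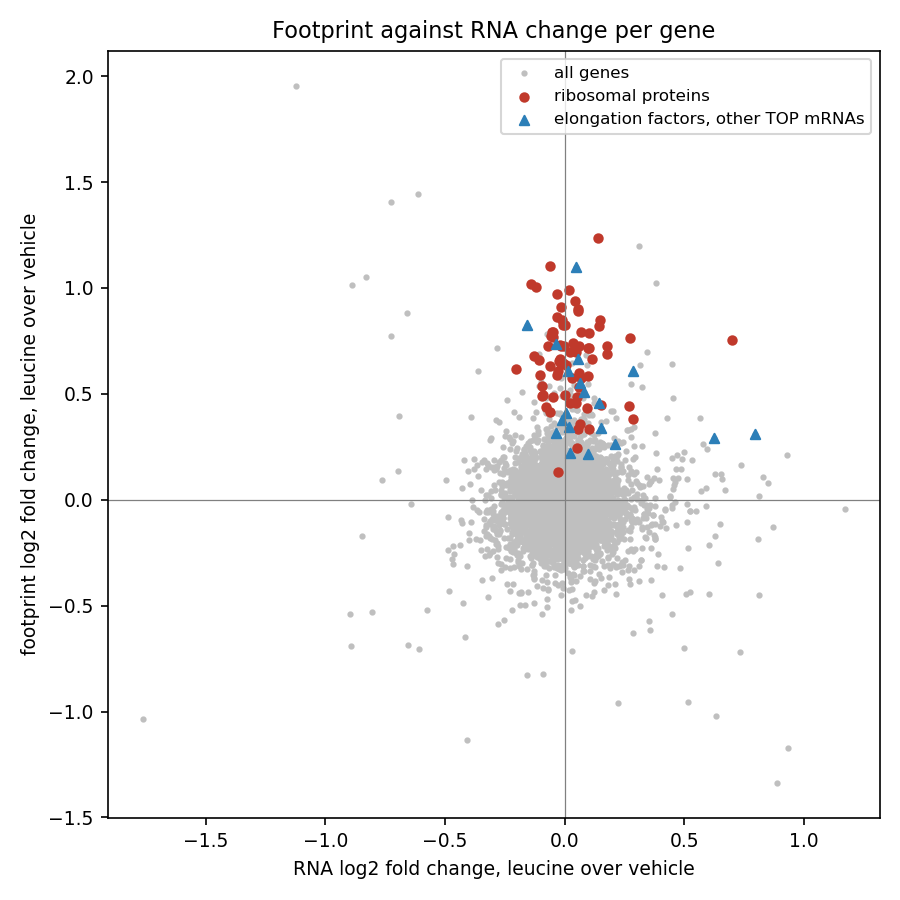
Log2 change (leucine minus vehicle) in RNA on the x axis and in footprints on the y axis for 6054 genes, 1 point per gene, with the 74 ribosomal protein genes in red and the 19 elongation factor and other TOP genes as blue triangles. All 74 red points lie above 0 in footprints, with a median of 0.68, while in RNA 39 of 74 lie above 0.

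The authors' deposited tables list more genes than the count table, and their values are the authors' own. In the authors' deposited footprint table, 84 genes were higher and 6 lower at an FDR under 0.05, and 655 had p under 0.05. Of those calls 80 were among the genes tested here, and 36 of the 46 genes called here were also called in the authors' deposited table. That authors' deposited table gives Rps2 a log2 change of 1.252 with an FDR of 8.44e-05, Eef2 1.11, Rplp0 1.01 and Rpsa 0.99, and it calls 57 ribosomal protein genes higher. Its lower genes, named here after their values were seen, were Spon2 (-1.23), Lcp2 (-0.997), Fat3 (-0.75), Tlr2 (-0.75), Arntl (-0.55) and 1 clone in the authors' deposited table. In the authors' deposited RNA table, 2 genes were higher, the small nucleolar RNAs Snord22 and Snord82, named after their values were seen, 0 were lower and 241 had p under 0.05.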

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

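The tests of other splits for the ribosomal protein medians and for the endothelial score, within the column sets, of those sets, and of fewer fibroblasts or endothelial cells were chosen only after the result was seen. Of 136 groups of libraries searched for a library far from the rest of its group, 9 held one; chance gives about 1 in 20, or 6.8. Leucine RNA library A3 was the highest of its group for the list scores of mTORC1 signalling (0.261, the others -0.111 to -0.0276), fast-fibre sarcomere (0.272, the others -0.0896 to 0.0231) and the circadian clock (0.308, the others -0.228 to -0.0309). It was the lowest for Rpsa (143 CPM, the others 187 to 211) and Eef2 (749 CPM, the others 961 to 1070). Sterol and fatty acid synthesis had a high RNA score in vehicle library B2 (1.33, the others -0.506 to -0.236) and in leucine library B2 (0.765, the others -0.273 to 0.00987). Leucine footprint library B2 was the lowest for smooth muscle markers (-0.12, the others 0.0386 to 0.127), and vehicle footprint library A1 for Mib1 (36.8 CPM, the others 39.7 to 40.7). The small nucleolar RNAs Snord22 and Snord82, outside the count table, each have a log2 change of 1.16 in the authors' deposited RNA table, with FDR values of 0.0059 and 0.0117, and are its 2 genes at an FDR under 0.05.

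Splits of the same libraries into groups of 5 and 6 show how often regrouping gives a result as large. There were 100 splits each, the real one included. A drawn split can still follow the treatment in part or in reverse. For called footprint genes 1 of 100 splits gave as many as the real 46. The highest other gave 17, in a split that kept 0 of the 5 vehicle libraries and so nearly mirrors the treatment. Chance is thus unlikely for that count. It is not excluded, since the splits did not keep the column sets and the count was not permuted within them. For 14 footprint lists past the preset test, 10 of 100 splits gave as many. The highest other, 16, came from splits that kept 4 or 1 of the 5 vehicle libraries and so hold part of the treatment difference. Chance cannot be excluded for the number of lists. The same holds in RNA, with 89 of 100 for 4 lists (highest other 15), and for efficiency, with 37 of 100 for 10 lists (highest other 17). Where the real count was 0 genes, any split gives as many, so the 100 of 100 splits in RNA (highest other 7) and 100 of 100 for efficiency (highest other 137) say nothing about chance. A split along the column sets called 1228 genes in RNA, 1316 in footprints and 379 for efficiency, against real counts of 0, 46 and 0, which points to a structure of the samples other than treatment. Within sets the footprint test called 0 genes in A and 1 in B.

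Ribosomal protein footprints had a median rise of 0.68, and 1 of 100 splits gave a median as far from 0 (real 0.6827, highest other -0.654). For efficiency 2 of 100 did (real 0.649, highest other -0.711). The highest others nearly mirror the treatment, with 0 of 5 and 1 of 10 vehicle libraries kept. By the share of splits, chance is unlikely for both medians. These splits did not keep the column sets; in an exact permutation within the sets, the footprint score of the list had p = 0.005 (two-sided, the smallest its 200 splits allow; adjusted p = 0.03 over 24 lists), and efficiency was not tested that way. Matched genes came from outside the translation lists and the mitochondrial ribosomal protein list. Those matched on coding length had a median footprint change of 0.00768 ± 0.00982 (SE), and those matched on RNA abundance -0.0244 ± 0.00687. These errors come from a bootstrap over genes and do not measure the spread between libraries. Both medians lay below 0.341, a bound computed from the list's observed median by a rule set beforehand. This argues against short coding sequences or abundant mRNAs as the whole cause. A difference between the column sets is argued against by the smaller of the set medians, 0.546. Reads shared with pseudogenes would be counted in vehicle and leucine libraries alike. The RNA score of the same list differed by 0.0257 ± 0.0958 (SE) against 0.655 ± 0.143 in footprints, so no rise was seen in RNA. That does not test shared reads within the footprint libraries, so it cannot decide this explanation. Such reads can also blur which single members rose, and no test here separates them. Leucine treatment, the planned comparison, stays open as a hypothesis.

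Fibroblast and matrix markers had a median footprint change of -0.20 with 20 of 23 negative. Fewer fibroblasts in the leucine samples would lower their RNA too, but the RNA score differed by 0.076 ± 0.199 (SE) against -0.189 in footprints, too wide a spread to decide, with leucine RNA library A1 at 0.627 and the other leucine libraries at -0.368 to 0.148, so a change in cells and a change in translation cannot be told apart. In the whole tissue, which no sort had divided, all 23 markers were measured. The RNA levels of the most abundant in vehicle were 1557 CPM for Gsn, 850.2 CPM for Col3a1 and 628.5 CPM for Col1a2. Another candidate explanation, fewer footprints on mRNAs of secreted and membrane proteins, also cannot be told apart from the rest: 91.3% of the list has a predicted N-terminal hydrophobic segment against 16% of all genes, and genes with one differed by -0.0297 from the others, not past the threshold in camera with an estimated correlation.

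Endothelial markers had a median RNA change of -0.17 with 9 of 10 negative. In the exact test 73 of 462 splits gave a score difference as far from 0 (real -0.231, highest other -0.422), so chance cannot be excluded. Fewer endothelial cells in the leucine samples would lower footprints too, and the footprint score differed by -0.0847 ± 0.0994 (SE), which cannot be told apart from either outcome. The tissue was whole muscle, and the most abundant markers in vehicle RNA were Flt1 at 55.9 CPM, Kdr at 49.4 CPM and Pecam1 at 48.1 CPM.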

How the results depend on the processing

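The settings that use the column sets, the mean count of at least 500 and DESeq2 with the set as a covariate were chosen only after the data had been seen. No paired analysis was possible because the columns carry no replicate numbers. The list scores of FoxO-linked and glucocorticoid-induced genes run alike in RNA and footprint libraries in column order. These lists share members and were picked after the data had been seen, and no measure of the likeness was computed. It is at most a weak hint that both assays share samples. Column order is no label, so no paired fit was made. Whether the 0 efficiency calls would hold in a paired fit is not known. No count filter and a mean count of at least 50 removed no gene and test nothing. In footprints 46 genes were called; of these 46 were also called with RLE scaling (48 higher, 4 lower), 45 without the 20 most abundant genes and 42 in the non-robust fit, while an adjusted p under 0.1 gave 91 higher and 13 lower. Upper-quartile scaling and limma-voom called 0 (smallest adjusted p 0.0665 and 0.0505), DESeq2 188 higher and 65 lower, the edgeR exact test 99 higher and 19 lower, the set as a covariate 46 higher and 9 lower, DESeq2 with the set 305 higher and 160 lower, set A alone 0, and set B alone 1 higher and 0 lower. With 1 library left out the counts ran from 0 to 84 higher and from 0 to 14 lower. No gene was called in 9 of 11 cases, and more genes were called in total without leucine A3 or leucine B3. A result counts as reversed if its sign changed and it passed the threshold in the main fit or in the setting. By that rule no named footprint gene reversed in any setting. Sign changes of results past the threshold in neither fit were not counted. With 1 library left out 1163 results kept their side of the threshold, 245 lost the call and 11 gained it. In other settings 872, 117 and 37 did. The ribosomal protein footprint median stayed between 0.611 and 0.754 with 1 library left out. In camera with an estimated correlation it was 0.6827 with adjusted p = 0.0643. There 0 footprint lists passed, and 7 passed with fry. Those 7 were ribosomal proteins, elongation factors and other TOP mRNAs, initiation factors, synthetases, ribosome biogenesis, fast-fibre genes and glycolysis. In RNA all settings called 0 genes except DESeq2 with the set (11 higher, 1 lower); 0 lists passed with an estimated correlation or fry, 6 in set A and 1 in set B, and from 2 (without leucine A1) to 10 (without vehicle A2 or leucine B2) with 1 library left out. The ribosomal protein RNA median ranged from -0.032 to 0.057 with 1 library left out. It was 0.104 in set A and reversed to -0.12 in set B, a set difference that did not pass (unadjusted p = 0.209, camera with an estimated correlation). Other RNA lists that reversed were fatty acid oxidation (-0.097 without vehicle A2, -0.13 without leucine B2, highest 0.098 without vehicle A1), oxidative phosphorylation (0.080 without vehicle B1, lowest -0.071 without vehicle A2), sterol and fatty acid synthesis (0.19 without vehicle B2, lowest -0.10 without leucine B2) and smooth muscle markers (0.043 in set B). For efficiency DESeq2 called 46 higher and 11 lower, with 3535 adjusted p-values not given, and 72 higher and 29 lower with the set, all other settings called 0, and 2 lists passed with an estimated correlation and 2 with fry. The cause of these differences between settings was not tested. At these depths counting error is small.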

Other observations

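The tests of leucine codons and TOP-like starts were written before their results were seen, while the values in the first 2 paragraphs were picked out after they were seen. The lists differed widely in how many footprints their mRNAs carried per RNA count. In vehicle muscle the mean log2 ratio was 1.71 ± 0.168 (SE, n = 5 libraries per assay) for fibroblast and matrix markers (3.27-fold), 0.977 ± 0.103 for chaperones and 0.917 ± 0.116 for smooth muscle markers, against -0.525 ± 0.067 for the ATF4 list and -1.58 ± 0.105 for ribosomal proteins (0.335-fold). Ribosomal proteins thus had the lowest ratio of the tested lists in vehicle muscle, at the 9.91st percentile of all genes by median, and at the 21.8th percentile in leucine muscle. The ratio was not corrected for coding length, with a median of 462 nucleotides in this list against 1476 over all genes. Reads shared with pseudogenes were not corrected for either.

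Small nucleolar RNAs, which guide modification of ribosomal RNA in the nucleolus, formed no list fixed beforehand and were not tested as a group. All 10 in the count table had a positive RNA value and a negative footprint value, and none passed in either assay; for Snora74a the efficiency change was -2.12 ± 0.55. In the authors' deposited RNA table, 70 of 74 such RNAs were positive, with a median of 0.646, and Snord22 and Snord82 were at an FDR under 0.05. In the list of sterol and fatty acid synthesis, which did not pass, the footprint values with the smallest p had wide errors and none passed, 1.01 ± 0.52 for Acly (adjusted p = 0.470), 1.96 ± 1.02 for the fatty acid synthase gene Fasn (adjusted p = 0.477), 1.41 ± 0.77 for Acaca (adjusted p = 0.501) and 1.44 ± 0.84 for Scd1 (adjusted p = 0.524), while RNA changes were -1.12 ± 0.99 for Fasn and -0.73 ± 0.75 for Acaca. The footprint score of this list differed by 0.544 in set B and by -0.0102 in set A. Its RNA median was -0.02, and 0.19 without RNA vehicle library B2, whose score of 1.33 was the highest of its group.

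One hypothesis was that mRNAs rich in leucine codons might gain footprints when leucine is given. Across 6013 genes the share of leucine codons and the footprint change had a Spearman rho of 0.0183, and 0.0441 outside the translation lists, so no such relation was seen; ribosomal protein genes hold 7.33% leucine codons against 9.62% over all genes. A second hypothesis was that a pyrimidine-rich transcript start could go with higher efficiency outside the translation lists. Genes with such an annotated start differed by 0.0253 in median efficiency change, not past the threshold in camera, but only 8.11% of ribosomal protein genes have one in this annotation, so the test cannot decide.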
